A study of Homo sapiens with 2 samples.

How the data were processed

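Human pancreatic islets were profiled by HITS-CLIP, in which RNA is crosslinked to protein by ultraviolet light and immunoprecipitated, here with an antibody against Argonaute, the protein that holds microRNAs (miRNAs) on their targets. There was 1 library of miRNAs and 1 library of mRNA fragments, per the labels. The antibody clone named in the labels differs between the 2 libraries, but whether the antibodies in fact differed is not known here. Neither library had a replicate, so no difference could be tested against replicate error, and no p-value across genes was computed.

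The libraries were prepared after published Argonaute HITS-CLIP protocols and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name cutadapt, an adapter trimmer, without a version, and the genome build hg19. The aligner, the mismatch setting, the treatment of duplicate reads and the way reads were divided between matches are not given in the sources used here. The deposited miRNA table gives an estimated count of reads and an RPKM value (reads scaled by length and by the library total) for each of 1919 mature miRNAs. The estimated counts deposited by the authors are mostly not whole: 18.6% of the miRNAs with reads had a whole value, within a tolerance of 1e-06, so reads with several matches appear to have been divided. The authors' RPKM values correspond to a library total of 40138681 reads for miRNAs and 27122628 for mRNAs, computed here from the ratio of count to RPKM and length. The deposited mRNA table gives estimated counts and RPKM for 67110 contigs, stretches of overlapping reads on spliced RefSeq mRNAs. In it 52.6% of the contig counts were whole and the smallest was 0.01. Duplicate reads without molecular identifiers are not independent molecules, so all intervals cover counting error only.

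The estimated counts were used as deposited and were rounded only to compute intervals. A miRNA's share is its percent of the 8174476 reads in the miRNA table, with an exact (Clopper-Pearson) 95% interval. For a miRNA at 0, a limit of 3 reads was taken, which is 3.67e-05% of the table. Members of a list or cluster were matched by miRNA number over all arms and copies. Seed families were chosen, with the sequence of 1 member each, together with the lists. The member names of each family were assigned once the names used in the table were known.

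In the mRNA table, 19014 of 19331 RefSeq identifiers were matched to a current gene symbol by their accession. The names came from a RefSeq table of the assembly GRCh38.p14, whose coordinates were not used. Because isoforms repeat the same contigs, each gene with a name was represented by its 1 transcript with most reads, which left 10405 genes with 5303106 reads. Transcripts on the Y chromosome were left out. Gene coordinates are those of the deposited file (hg19). Their starts were read as counted from 0 and are printed counted from 1, since the last contig ended at the last base of that span in 4 transcripts and past it in 0. Contig positions are in nucleotides along the spliced transcript. They were taken as counted from its 5' end: isoform pairs that share only this end had 69.1% of their 1232 shared contigs at equal positions, against 0.288% of 11794 for pairs that share only the 3' end. Covered fraction means the summed length of a transcript's contigs as a percent of the position where its last contig ends. Transcript lengths, coding regions and untranslated regions were not used here, so no contig is assigned to one.

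The lists of genes and miRNAs were fixed before the data were examined, as were most of the alternative settings; the lists and settings added later are named as such. For each gene list, the median of reads over its members with contigs was placed among the medians of 10000 random lists of equal size drawn from the 10405 genes. The resulting percentile describes this library and is not a p-value. Percentiles above 97.5 or below 2.5 are called apart from random lists. These limits, unlike the use of random lists, were set when the data were already at hand. Tested on simulated data for the mRNA library (10405 genes, 200 of them raised, 100 lists of 15 genes), 41 lists raised 4-fold and 69 raised 16-fold passed the upper limit. In the same 2 simulations, 4 and 1 of 100 unchanged lists passed either limit, so a list that does not stand apart may still be raised. The 16-fold simulation was added after the 4-fold result was seen. The text names the 25 miRNAs and the 25 named genes with most reads, the 3 contigs with most reads among those genes, the 10 leading members of the MEG3-DLK1 cluster, and the 3 leading miRNAs or 4 leading genes of each other list. Some genes that this rule takes are not reported here. Other items are named as chosen after their values were seen.

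Intended analyses that need sequence or transcript structure were not run. These are the share of reads per transcript region, seed-match enrichment, its relation to family abundance, and seed sites in IAPP and TP53INP1. Alternatives tried were other denominators, a minimum of 10 reads, collapsed arms, other per-gene summaries and random lists matched on transcript extent. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.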

Results

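The study set out to identify miRNA-target pairs in human islets, within work on the MEG3-DLK1 miRNA cluster, an imprinted group of miRNA genes on chromosome 14. The data comprised 1 Argonaute HITS-CLIP library of miRNAs and 1 of mRNA fragments. The miRNA table held 8174476 reads, 20.4% of the library total that the authors' RPKM values imply. From the mRNA table, 5303106 reads on 10405 named genes were kept, with 1 transcript per gene, which is 19.6% of its implied total. Transcripts without a gene name are not in that sum. All values are from single libraries without replicates, and every interval covers counting error only.

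The first question was which miRNAs were read in the Argonaute library. A few miRNAs took most of the reads. miR-374b-5p led with 1138525 reads, or 13.9% of the table (95% interval 13.9 to 14.0), followed by miR-22-3p with 13.5% and miR-186-5p with 12.3%. These 3 held 39.7% of all reads and the leading 10 held 74.2%. Next came miR-3065-3p with 8.81%, miR-708-5p with 7.19%, miR-136-3p with 5.88%, miR-221-3p with 4.51%, miR-193b-5p with 3.15%, miR-23b-5p with 3.07% and miR-320a with 1.89%. Shares between 1% and 2% were found for miR-101-3p (1.70%), miR-192-5p (1.62%), miR-145-3p (1.13%), miR-17-3p (1.07%), miR-106a-5p (1.07%) and miR-126-3p (81967 reads). The remaining leaders were miR-539-3p, miR-23a-3p, miR-376a-3p, miR-191-5p, miR-217, miR-33a-3p, miR-29b-3p, miR-33b-5p and miR-142-3p, from 0.931% down to 0.442%. Of the mature miRNAs listed, 456 had reads, 351 had at least 10 and 1463 were at 0.

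**Figure D1:**
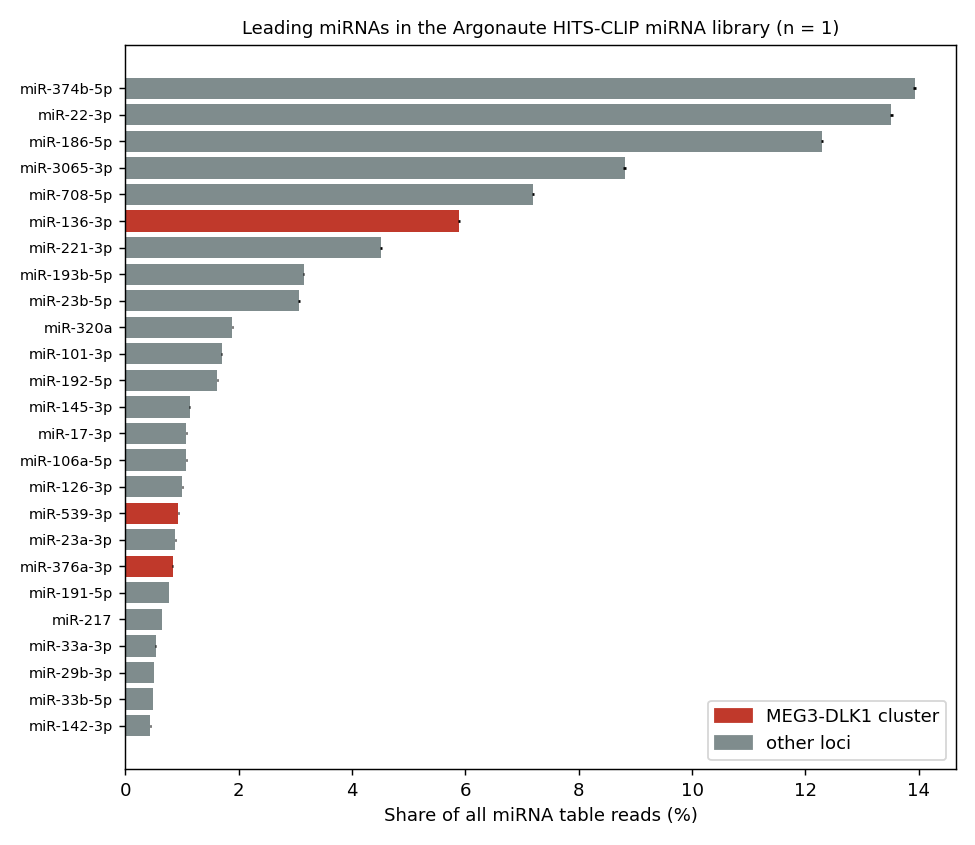
Share of all reads in the miRNA table (percent, horizontal axis) for the 25 miRNAs with most reads, as bars with exact 95% intervals that are narrower than 0.1 percentage points; red bars are members of the MEG3-DLK1 cluster and grey bars are other miRNAs. miR-374b-5p leads at 13.9%, and 3 cluster members are among the 25, the highest being miR-136-3p at 5.88%.

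Many hairpins were read mostly from 1 arm. Among 96 hairpins with both arms listed and at least 1000 reads, 38 had over 90% of their reads on the 5' arm, 35 had over 90% on the 3' arm, and 23 were mixed. miR-136 had 481029 reads on the 3' arm and 7.5 on the 5' arm. miR-145 had 92618 on the 3' arm against 1789 on the 5' arm, and miR-17 had 87671 against 2343. The arms of these hairpins were named after their values were seen.

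The MEG3-DLK1 cluster, named in the title of the series, held 671412 reads, or 8.21% of the table (95% interval 8.19 to 8.23). Reads were found for 38 of its 74 listed mature miRNAs. miR-136-3p alone gave 71.6% of the cluster's reads, and without it the cluster held 2.47% of the remaining reads. miR-539-3p followed with 76081 reads and miR-376a-3p with 68015, which were 0.931% and 0.832% of the table. The other leading members were miR-369-5p (23570 reads), miR-376a-5p (9281 reads), miR-377-3p (3974 reads), miR-1185-5p (2678 reads), miR-539-5p (2433 reads), miR-299-5p (870.3 reads) and miR-377-5p (494.7 reads). The cluster members miR-495 and miR-410 were at 0 of 8174476 reads, which allows a share of up to 3.67e-05%. miR-432-5p had 365 reads and miR-127-3p had 97.3. These 4 were named after their values were seen. The other large imprinted miRNA cluster, on chromosome 19 and analysed with the miR-371 to miR-373 group, held 0.0208% of the table. Its leading members were miR-518a-5p (769 reads), miR-520a-5p (588 reads) and miR-522-5p (0.00245% of the table), and 19 of its 63 listed miRNAs had reads.

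miRNAs known from particular cell types were read at different levels. The neuroendocrine list, which holds miR-375, an miRNA known to be abundant in beta cells, had 0.438% of the table (95% interval 0.433 to 0.442). Its leaders were miR-183-5p (14651 reads), miR-153 (7297 reads) and miR-7-5p (4056 reads). miR-375 itself had 512.5 reads, or 0.00627%, and ranked 185. The acinar list (digestive enzyme-secreting cells) held 1.15%, led by miR-217 (52594 reads), miR-216b (26407 reads) and miR-148a-3p (11564 reads). The mesenchymal list held 1.92%, led by miR-145-3p, miR-199a-3p (23867 reads) and miR-199b-3p (11826 reads). The endothelial miRNA miR-126 held 1.04% over its arms, of which miR-126-3p had 81967 reads and miR-126-5p had 3152. The epithelial list held 0.746%, led by miR-141-5p (26793 reads), miR-141-3p (23730 reads) and miR-200c-5p (5445 reads). The blood list held 0.491%, led by miR-142-3p (36161 reads), miR-142-5p (2939 reads) and miR-144-5p (654.8 reads). The let-7 and miR-98 list, over all arms, held 0.173%, led by let-7a-5p (3279 reads), let-7d-3p (2912 reads) and let-7f-2-3p (1928 reads). As a seed family, a grouping explained below, let-7 and miR-98 held 0.0683%. The muscle list held 0.00139%, with 110.5 reads for miR-133a, 3.5 for miR-1 and 0 for miR-133b. In the liver list miR-122-5p had 0.50 reads and miR-122-3p had 0.

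Grouped by seed, the stretch of a miRNA that pairs with its target, miR-22 was the highest of the 57 families fixed beforehand, with 13.5% of the table. The miR-101 family followed with 1.70% and the family of miR-17-5p with 1.19%. Many leading miRNAs belonged to none of these families. Among them were miR-374b-5p, miR-186-5p, miR-3065-3p, miR-708-5p, miR-136-3p and miR-221-3p, each with more reads than the miR-101 family. Members of 1 family differed widely. miR-23a-3p had 72124 reads and miR-23b-3p had 16, and miR-29b-3p had 41268 reads against 49.6 for miR-29a-3p. In 11 of 19 families with several members the highest had over 100 times the reads of the lowest, with 3 reads as the lower limit for a member below that. miR-21-5p, a widely abundant miRNA, had 5 reads against 1083 for miR-21-3p, miR-200c-3p had 11 and miR-30e-5p had 4. The miRNAs named in these last comparisons were chosen after their values were seen. Whether the ranking of reads follows the amounts held by Argonaute was not tested here.

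The second question was which mRNAs carried Argonaute-associated fragments. Among genes matched to a name, the most read was FOS, an immediate early transcription factor, with 37088 reads, or 0.699% of gene reads (95% interval 0.692 to 0.706). REG1A, a secreted protein of the exocrine pancreas, had 25982 reads, MCL1, a survival factor of the BCL2 family, had 24537, and PRSS1, which encodes trypsinogen, had 24284. GCG, the glucagon gene, had 20549 reads and RFX6, a transcription factor of islet development, had 16693. The zinc finger gene ZNF91 had 21838 reads in 26 contigs. CANX, an endoplasmic reticulum chaperone, had 15984 reads, REG1B had 15816, TTR (transthyretin) had 15716, DST had 15701, TSPYL1 had 15364 and ACTB had 15107. Other leaders were FAT1, MACF1, CPB1, GOLGB1, ACTG1, THBS1, SPTBN1, ARRDC3, CLU and H3-3B, from 14561 down to 10947 reads. Values of REG1A and REG1B, ACTB and ACTG1, PRSS1, ZNF91 and H3-3B are uncertain because near-identical genes share reads. The 25 leading genes held 7.72% of gene reads, the median gene had 80.0 reads, and 1531 genes had at least 1000.

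Contigs had a median length of 61 nt, with quartiles of 39 and 92 nt. The highest 1% of contigs (356 of 35618) held 23.3% of the reads. Among these genes, the contig with most reads lay at positions 1701 to 1983 of the FOS transcript and had 35562 reads, 95.9% of the gene. The next were REG1A from 37 to 774 with 25982 reads and PRSS1 from 11 to 813 with 24284 reads. In RFX6 (chromosome 6, 117198376 to 117253326, plus strand) a single contig at positions 3213 to 3445 had 16475 of the gene's reads, or 98.7%. In TSPYL1 the contig at 3238 to 3421 had 99.7% of the reads. These last contigs were named after their values were seen.

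The random lists were not matched on the amount of each mRNA in the tissue. Here and for the later gene lists, a high percentile therefore does not separate Argonaute binding from abundance. Hormone and secretory granule genes stood above all 10000 random lists, with a median of 2105 reads over 16 members with contigs (of 17 listed). Random lists had a median of 83.6, and 15 of the 16 members lay above the median gene. GCG and TTR led, followed by SCG2 with 10733 reads and CHGB with 9073, both granins of the secretory granule. INS, the insulin gene (chromosome 11, 2181009 to 2182439, minus strand), had 7833 reads in 1 contig from position 2 to 465, and was named outside the rule after its value was seen. Genes of exocytosis and stimulus-secretion coupling also stood above all random lists, with a median of 1326 reads. Its leaders were MTPN (3983 reads), SNAP25 (3051 reads), SYT7 (2820 reads) and G6PC2 (2633 reads), and 16 of 20 members lay above the median gene. MTPN overlaps a second annotated transcript with the same reads. Islet transcription factors had a median of 351.0 reads, at percentile 95.2, which does not pass the upper limit. The list lay at 35.3 by number of contigs, at 66.1 when only contigs with at least 10 reads were used, and at 97.6 among random lists matched on transcript extent, a comparison chosen after seeing the data. RFX6 led, and ISL1 had 1194 reads and NEUROD1 had 1043.

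Acinar markers had the highest median of the gene lists, 4880 reads, above all random lists, and all 20 members lay above the median gene. REG1A, PRSS1 and REG1B led it. The list lay at percentile 80.5 when contigs were counted in place of reads. It held 2.90% of gene reads, against 1.56% for hormone and granule genes. Ductal markers had a median of 364 reads at percentile 91.2 (86.7 by number of contigs and 97.6, past the limit, among the matched random lists), led by CFTR (2114 reads), ANXA4 (1736 reads), KRT7 (1478 reads) and SOX9 (1327 reads). Mesenchymal and stellate markers lay at percentile 75.1 by reads, 98.4 by number of contigs and 25.6 with only contigs of at least 10 reads, with 7 of 11 above the median gene, led by COL1A1 (3435 reads), COL3A1 (3432 reads), SPARC (2036 reads) and COL6A1 (1085 reads). Endothelial markers had a median of 99.0 reads at percentile 48.7, led by FLT1 (1748 reads), CDH5 (319 reads), VWF (166 reads) and ENG (32.0 reads). Of 10 blood and immune markers 3 had contigs, CD74 with 103 reads, CD68 with 27.5 and PTPRC with 0.05, a median at percentile 36.2. Housekeeping and translation genes had a median of 2952 reads, above all random lists, led by ACTB, EEF2 (10000 reads), EEF1A1 (7676 reads) and RPL3 (3864 reads).

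**Figure D2:**
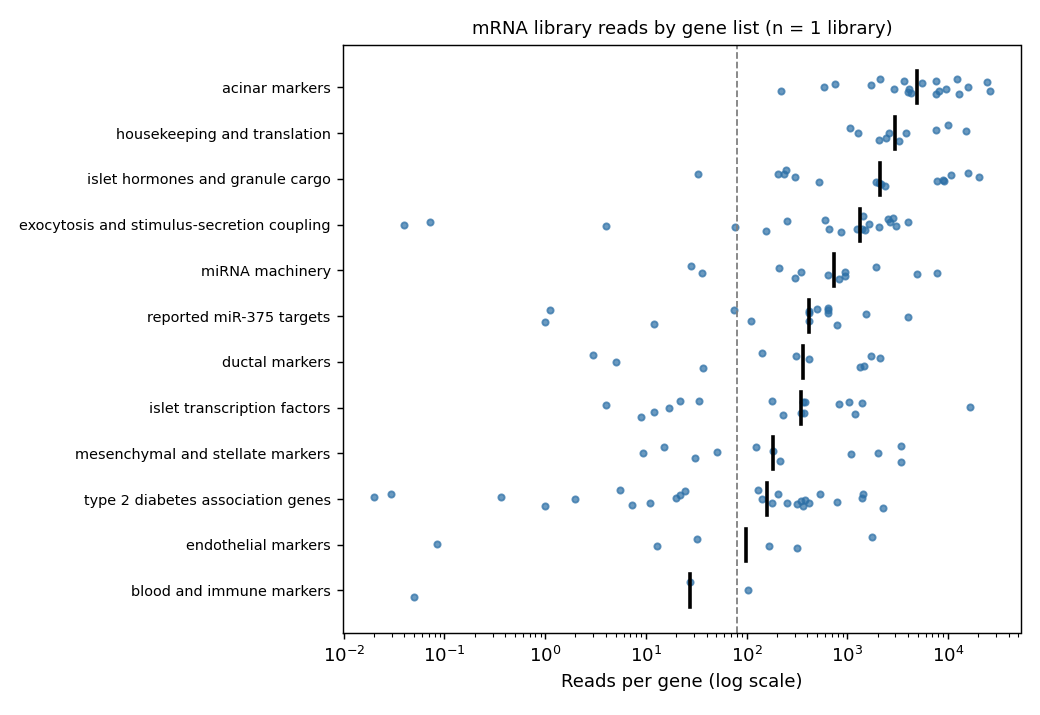
Reads per gene in the mRNA library (horizontal axis, log scale) for each gene list with at least 3 members that have contigs; each point is a gene, the black bar is the list's median and the dashed line is the median of all 10405 genes, 80.0 reads. Acinar markers have the highest median, 4880 reads, and blood and immune markers the lowest, 27.5 reads.

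Genes of the miRNA machinery had a median of 740.0 reads, at percentile 99.4, and 10 of 12 lay above the median gene. DICER1, the enzyme that cuts miRNA precursors, had 7778 reads, TNRC6A and TNRC6B, partners of Argonaute, had 4959 reads and 0.0362% of gene reads, and AGO1 had 954. The list no longer passed the limit among random lists matched on transcript extent (percentile 93.5) or when only contigs with at least 10 reads were used (percentile 94.8). Genes associated with type 2 diabetes had a median of 161 reads at percentile 79.9, with contigs for 26 of 37. TP53INP1 (2259 reads), SLC30A8, the zinc transporter of insulin granules (1418 reads), and NOTCH2 (789 reads) were among its leaders. Targets reported for miR-375 had a median of 415 reads at percentile 96.4 (99.3, past the limit, by number of contigs and 80.7 with only contigs of at least 10 reads), led by MTPN, YWHAZ (1532 reads), KLF5 (793 reads) and GPHN (651 reads). From the MEG3-DLK1 locus, DLK1 had 178 reads in 2 contigs, at percentile 60.2 of random genes. MEG3, a non-coding transcript, was not analysed here, since every identifier in the table used is of an mRNA.

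The study is known to have followed IAPP and TP53INP1 as targets of cluster miRNAs, so they are not independent of these libraries. IAPP encodes islet amyloid polypeptide (chromosome 12, 21525802 to 21532914, plus strand) and had 2055 reads in 11 contigs. Its highest contig, at positions 449 to 572, had 1122 reads, or 54.6% of the gene. Contigs at 1553 to 1621 and 1748 to 1847 had 321 and 256 reads. TP53INP1, a p53-induced nuclear protein gene (chromosome 8, 95938200 to 95961615, minus strand), had 2259 reads in 8 contigs. The contig at positions 5556 to 5628 had 1579 reads, or 69.9% of the gene, and that at 2350 to 2439 had 443 reads. Both genes lay above the median gene, and their median lay at percentile 95.8 of random pairs. Which miRNA was paired with each contig was not analysed here.

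**Figure D3:**
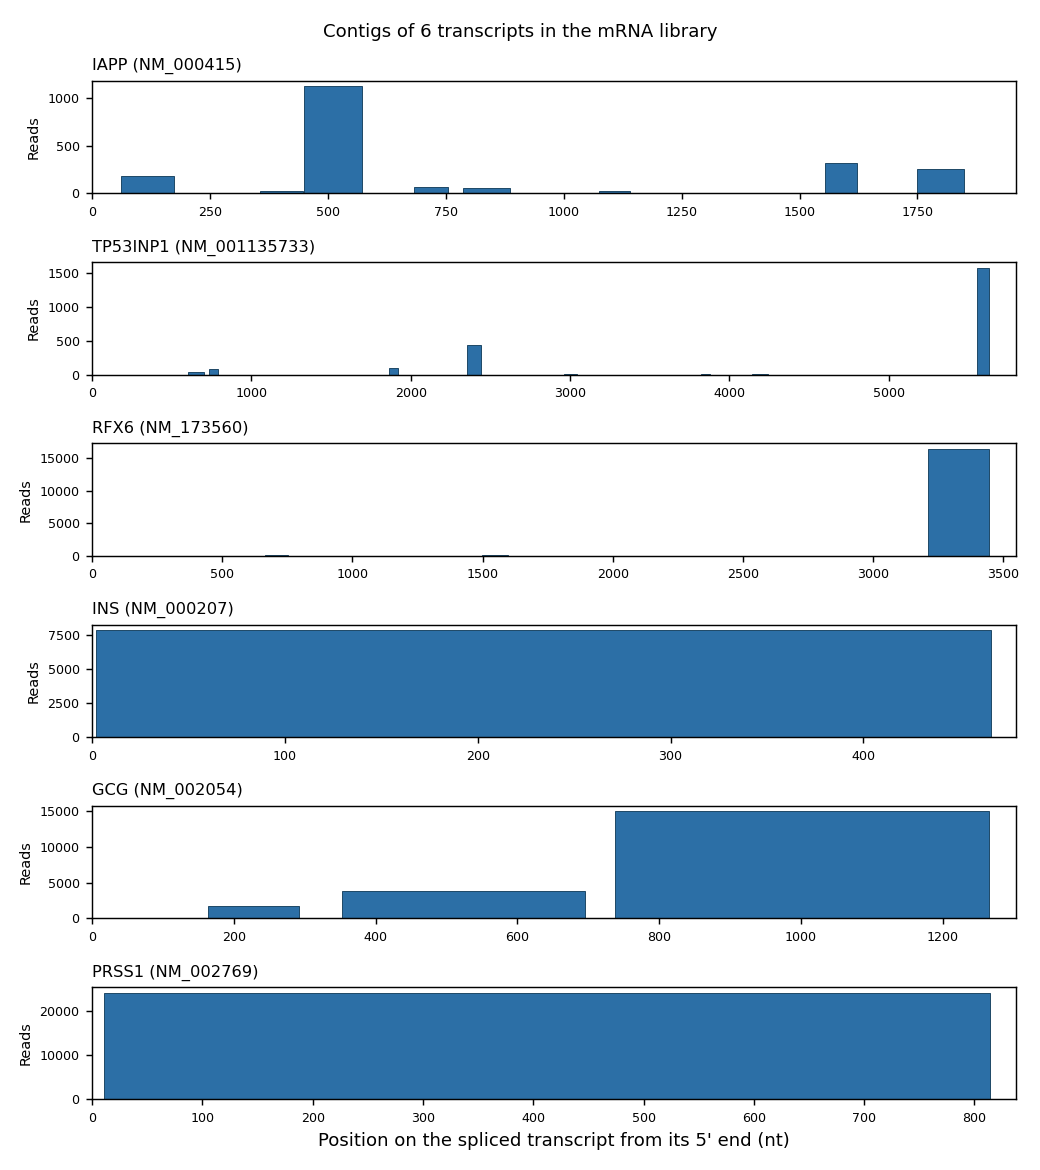
Contigs of 6 transcripts, drawn at their positions on the spliced transcript in nt from its 5' end (horizontal axis) with the reads of each contig as bar height; axes differ between panels and each ends just past the last contig. The reads of RFX6 lie almost wholly in 1 contig (98.7%), those of IAPP and TP53INP1 are split between several narrow contigs, and INS and PRSS1 are each covered by 1 contig over 464 and 803 nt.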

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

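Reads lay on transcripts that entered no gene comparison because their identifiers matched no gene name in the tables used. The transcript NM_001190470 (hg19, chromosome 5, 79945819 to 79946854) had 171534 reads in 2 contigs that covered 97.6% of its extent. NM_001190702 (chromosome 11, 10529434 to 10530723) had 162938 reads in 5 contigs that covered 92.7%. These values are 4.63 and 4.39 times the 37088 reads of FOS, the highest gene with a name. Both are far above 3 reads, the limit that a count of 0 allows.
Another transcript without a gene name (chromosome 17, 22022437 to 22023991) had 32147 reads in 9 contigs, 0.867 times the reads of FOS. These transcripts were singled out after their values were seen, and no explanation was tested. The ratios to FOS therefore do not show that these transcripts were bound by Argonaute.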

How the results depend on the processing

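The denominator implied by RPKM, the random lists matched on the end of the last contig and the use of all distinct contigs of a gene were chosen after seeing the data. Settings on transcript regions, seed matches and introns were not run, since they need sequence or transcript structure and the table used gives positions on spliced mRNAs. With the library total implied by RPKM as the denominator miR-374b-5p held 2.84% and the MEG3-DLK1 cluster 1.67%. Without miR-374b-5p, miR-22-3p led with 15.7%, the cluster held 9.54%, and the other list shares were 0.0241% (chromosome 19 cluster), 0.508% (neuroendocrine), 0.867% (epithelial), 1.33% (acinar), 2.23% (mesenchymal), 1.21% (endothelial), 0.570% (blood) and 0.201% (let-7). The cluster made up 8.33% of miRNAs with reads when each counted once, and 2.47% of reads without miR-136-3p. A minimum of 10 reads moved neither share beyond its interval, and collapsing arms did not move that of the leader. For gene lists, counting contigs put acinar markers at percentile 80.5, mesenchymal markers at 98.4 and miR-375 targets at 99.3. Random lists matched on the end of the last contig put islet transcription factors at 97.6, ductal markers at 97.6 and miRNA machinery at 93.5. A minimum of 10 reads per contig put miRNA machinery at 94.8, mesenchymal markers at 25.6, islet transcription factors at 66.1 and miR-375 targets at 80.7. The hormone, exocytosis and housekeeping lists stayed past the upper limit under every alternative run. The cause of these changes was not tested. Of the 25 leading genes, 16 remained among the leading 25 by highest contig and 4 by number of contigs, against 25 with the minimum of 10 reads and 21 with all distinct contigs of a gene. No paired analysis was possible because each kind of library had 1 sample. Depth did not limit the leading values, but 3276 of 10405 genes had under 10 reads, and without replicates the spread between preparations is unknown.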

Other observations

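The tests on miRNA names, first bases, islet cell content and covered fractions were chosen after the results were seen, and the first 3 replaced earlier tests whose results were known, that on first bases 3 times. The lists of early response, folding and ribosomal protein genes were prompted by leading genes already seen, which were left out of them, and were set before the values of their members were looked up. Early response genes, a list prompted by FOS, MCL1 and THBS1, had a median of 1554 reads over 19 members with contigs, above all random lists (percentile 100), and 18 of 19 lay above the median gene. CXCL8, a chemokine, EGR1 and FOSB, both immediate early transcription factors, and KLF6 led, at ranks 109, 225, 228 and 247. DUSP1, a phosphatase gene, had 91.5% of its reads in 1 contig. Whether the tissue responded to isolation or culture was not tested.

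Endoplasmic reticulum folding genes, without CANX and HSP90B1, had a median of 801 reads over 16 members (percentile 99.9 of random lists), and 15 lay above the median gene. HSPA5, the main chaperone of this compartment, ranked 71 and ERO1B, a disulfide oxidase of the pancreas, ranked 93. Ribosomal protein genes had a median of 461 reads over 20 members (percentile 98.9), led by RPL15 and RPS3A at ranks 253 and 338, and their values are uncertain because pseudogenes share reads.

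miR-375 held 0.00627% of the miRNA table, and let-7 with miR-98 held 0.173% over all arms. Both miR-375 and let-7 are known to be abundant in islets. The let-7 and miR-98 seed family held 0.0683%. miR-21-5p, also widely abundant, had 5 reads. No shift of all names by up to 20 rows gave both miR-375 and let-7 more than 0.172%. In 1 direction let-7 alone never passed 0.171% and fell to 0, so the test could not decide there. In the other, let-7 reached 3.42% but miR-375 at most 0.832%, which argues against a shift that way. The test of both shares replaced another after that one's result was seen, because the other's margin was narrow. Of 24 pairs of equal values, 18 joined near-identical miRNA copies with names in place and 15 after a shift by 1 row. A shift of 3 rows, in the direction left undecided, gave miR-375 alone 13.9%, but joined near-identical copies in only 10 of the 24 pairs. Among the shifts tried, near-identical copies were joined in most pairs with names in place. A shift of part of the table stays open, and the shares of miR-375 and let-7 do not decide on a shift of the whole table in that direction. A bias against miRNAs that start with U is a candidate explanation that the values do not decide, since its test was replaced repeatedly with earlier results known. Among broadly expressed families without let-7 and miR-21, the 11 starting with U had a median of 12819 reads and the other 5 of 72140. This gap of -0.750 on the log10 scale was reached by 1.51% of all 4368 relabellings, one-sided. With 1 member per family the share was 4.88%, close to the limit of 5%. Among MEG3-DLK1 families, whose medians were near 0, the share was 29.0%. Over all 57 families, whose classes differ in first base, the gap was 1.12 the other way. Members of the U-starting families miR-29 and miR-30 differed over 100 times, so the family's first base alone does not set the reads. A low share of islet cells could bear on miR-375 but not on let-7, which is not specific to islets. The mRNA library leaves this possibility open. Islet transcription factors lay at percentile 95.2, or between 35.3 and 97.6 under other settings. Exocytosis genes and hormone and granule genes lay at 100, but so did acinar markers and housekeeping genes. Such percentiles rank genes within 1 library and do not measure a share of cells. Hormone and granule genes are also so abundant per cell that a low share could hide. Acinar markers had a higher median than hormone and granule genes (4880 against 2105 reads). Other biases of ligation, trimming or read assignment may contribute and were not tested, and no biological explanation was tested.

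Acinar transcripts were covered along a median of 89.96% of their extent, housekeeping genes along 74.0% and hormone and granule genes along 49.7%. Each lay at percentile 100 of random lists matched on reads. Islet transcription factors, at 10.3%, lay at percentile 86.0 and ductal markers, at 16.2%, lay at 98.6. Exocytosis genes, though above all random lists by reads, were covered along 10.97% (percentile 61.5). Genes of the miRNA machinery were covered along 8.87% (percentile 34.3). Many reads thus did not always go with wide coverage. Matching also on the end of the last contig raised the random median for the acinar list from 15.01% to 42.04%, so short extent could account for part of the gap, but the list stayed at percentile 99.96, although some matched pools held only 8 genes, and ductal markers fell to 88.5. A candidate explanation for the rest is that fragments of abundant mRNAs add a spread background to the Argonaute footprints. The percentile of 100 matched on reads alone restates the coverage that prompted this explanation, so it gives no support to it. A library without immunoprecipitation, which would decide it, was not analysed here, and no biological explanation was tested.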
